A study of Homo sapiens with 2 samples.

How the data were processed

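RNA was measured by sequencing in 2 libraries of A549 cells, a human lung adenocarcinoma line of alveolar epithelial type. One library came from control cells and the other from cells carrying a short hairpin RNA against the long non-coding RNA GUARDIN. The title of the control, ctrl, does not say whether those cells carried a hairpin. If they did not, effects of carrying any hairpin cannot be told apart from those of the knockdown. Per the labels' protocols, total RNA was extracted with TRIzol, checked for integrity, cleaned and treated with DNase, and libraries followed standard Illumina methods. Bowtie version 0.12.2 and the builds hg38 and mm8 are named in the submitters' processing notes, without their roles. The read counter, the annotation release, the strand setting, the sequence of the hairpin and the time after its delivery are not given in the sources used here.

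The deposited table lists, per the file headers, a count and an FPKM value per gene and library, and its first lines name the column that belongs to the control and the column that belongs to the knockdown. The counts are raw whole numbers over 50868 Ensembl genes and were used as deposited. The FPKM values were made by the authors: in 100.0% of the 19664 genes counted in both libraries, the deposited FPKM column and count column gave the same gene-model length in both libraries, within 0.1%, when FPKM was taken as the count scaled by gene length and by the column's total. That length was used as the gene-model length below. For some genes it exceeds the locus itself: it was 7019 bases for PSMB4, at 151399534 to 151401944 on chromosome 1. It is therefore not the length of a single transcript of such genes, and how it was formed is not given. Trends with it may hold more than transcript length. Of the gene IDs, 98.5% were found in GENCODE release 29, which is on GRCh38, and all of these lay on the same chromosome there, 94.9% of them at the same start and end. Coordinates are those of the table, on GRCh38 and counted from 1. Gene types and strands were taken from GENCODE release 29 by gene ID.

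The control library held 12704000 counts and the knockdown library 12450625. CPM is the count scaled by the library total times a TMM factor. The factors came from edgeR 4.0.16 in R 4.3.3 and were 0.964 for the control and 1.04 for the knockdown. On this scale 3 counts corresponded to 0.245 CPM in the control and 0.232 CPM in the knockdown. The TMM scaling moved every log2 ratio down by 0.11 relative to library totals. The deposited FPKM lacks it, so ratios from FPKM are higher by that amount before the pseudocount. Ratios are knockdown over control, as log2 of CPM plus a pseudocount of 1, for the 14305 gene symbols with a mean of at least 1 CPM. Where several rows had 1 symbol, the row with the highest mean was kept. This log2 ratio understates differences of genes with few counts. A fold is the ratio of scaled counts without a pseudocount, and its 95% interval is the exact binomial interval of the count in 1 library out of the sum of both. Intervals cover counting error only. They take reads as independent, which reads without molecular identifiers may not be, so the intervals may be too narrow even for counting error.

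Each group had 1 library, so no difference has a replicate check, and no p-value or standard error of a difference between the groups is given. Random lists, shuffles and bootstraps over genes describe these 2 libraries only. A gene was called different at 2-fold or more on the log2 scale with the pseudocount. In a simulation with counting noise alone, 0 genes of 14284 reached 2-fold higher and 2 reached 2-fold lower. In simulated data for this comparison 14297 genes passed the filter. Of the genes changed 3-fold 100 of 100 were recovered, as were 100 of 100 changed 4-fold, and 1 of 14097 unchanged genes was called. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery was not measured for genes between the filter and that level. The pseudocount shrinks ratios there, so these counts do not show recovery for such genes.

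Gene lists for pathways, cell types and the targeted locus were fixed before the data were examined, 42 in all. The median log2 ratio of each list with at least 5 measured genes was placed among the medians of 10000 random lists of the same size, drawn with replacement from 20 bins of mean CPM. A list below the 2.5th or above the 97.5th percentile is said to stand apart, as a description of these libraries. Of 40 lists ranked, about 2 would do so by chance if genes varied independently. Genes of a pathway may vary together, so the rate by chance between these libraries is not known. In the simulation with 200 changed genes, 12 of 200 random lists stood apart. After a shift of 0.3 on the log2 scale 200 of 200 did. Unchanged genes there carried counting noise only. In these libraries random medians ranged from -0.33 to 0.32 for the NF-kB list, so the simulation does not show how often such a shift would be found.

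The named genes followed a rule fixed in advance. They are the 12 protein-coding genes with the highest and the 12 with the lowest log2 ratio at a mean of at least 5 CPM, up to 4 members of each list that stood apart, up to 2 of each other list, 10 genes of the published GUARDIN, p53 and lamina work, and the genes of the targeted locus. Some genes that this rule names are not reported here. The alternatives planned were pseudocounts of 0.1 and 5, no filter, a mean of at least 5, median-of-ratios scaling, summing rows of 1 symbol, the deposited FPKM, and random lists not matched on expression. Removal of the trend with gene-model length in 50 bins was added after seeing the data, as were random lists matched on mean CPM and mature transcript length in 10 bins each. Mature length is the median over protein-coding transcripts of GENCODE release 29, and lists with it for fewer than 80% of their measured genes were left out there. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

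Counts of near-identical copies are uncertain. The processed pseudogene EEF1A1P5 held 80990 control counts against 20913 for EEF1A1, and processed pseudogenes together held 3.75% of the control and 2.67% of the knockdown counts. Reads of overlapping genes on opposite strands cannot be told apart without the strand setting.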

Results

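Gene expression was measured in 1 library of control A549 cells and 1 library of A549 cells with a hairpin against GUARDIN, a p53-responsive long non-coding RNA. The comparison asks which genes differ after knockdown of this RNA. The control library held 12704000 gene counts over 21774 detected genes, and the knockdown library held 12450625 over 21824. Mitochondrial genes took 13.7% of the control counts and 15% of the knockdown counts, and the 10 most counted genes took 15.4% and 14.8%. With 1 library per group there is no replicate error, and the intervals below cover counting error only.

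The targeted RNA was counted too few times to measure its reduction. The transcript published as GUARDIN corresponds, from background knowledge, to RP3-510D11.2 (ENSG00000234546, chromosome 1, 9182004 to 9196284), which had 15 counts in the control (95% Poisson interval 8.40 to 24.7) and 6 in the knockdown (2.20 to 13.1). This was 2.64-fold lower in the knockdown, with an interval of 0.967 to 8.29 that includes no difference. A reduction was therefore not detectable at this depth. The gene lies within MIR34AHG, the host gene of the microRNA miR-34a, on the opposite strand (ENSG00000228526, chromosome 1, 9148011 to 9196983). MIR34AHG had 54 and 78 counts, a fold of 1.37 (0.956 to 1.98), and without a stated strand setting reads of the 2 genes cannot be told apart where they overlap. Among the flanking genes, GPR157 was 1.66-fold higher (1.30 to 2.13) and the glycolytic enzyme gene ENO1 was 1.5-fold lower (1.48 to 1.52). H6PD and SLC25A33 were each 1.19-fold higher (intervals 1.05 to 1.35 and 0.889 to 1.61), SPSB1 was 1.09-fold higher (0.925 to 1.29) and TMEM201 1.07-fold lower (0.909 to 1.27). SLC2A5 had 1 and 2 counts, SLC2A7 had 1 and 0, and CA6 had 0 in both. The 7 ranked genes of this locus had a median log2 ratio of 0.23, within the range of random lists.

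Of 14305 genes, 932 were at least 2-fold higher in the knockdown library and 591 at least 2-fold lower, of which 830 and 476 were protein-coding. The gene with the highest ratio among those named, ANKRD33B (chromosome 5, 10564330 to 10657816), went from 17 to 718 counts, 40.0-fold higher (24.8 to 69.1). HSPA6, a stress-inducible HSP70 gene (chromosome 1, 161524540 to 161526910), went from 8 to 326 counts, 38.6-fold (19.4 to 90.3), and HSPA1A (chromosome 6, 31815464 to 31817946) from 1024 to 9657, 8.94-fold (8.38 to 9.55). PDP2, which encodes a phosphatase that activates pyruvate dehydrogenase, was 27.0-fold higher, and the mitochondrial carrier gene SLC25A36 was 18.9-fold higher. CRAMP1 was 13.2-fold higher and FAM129A 12.3-fold higher. NIPA1, UHMK1, the histone methyltransferase gene KMT2A, GABARAPL1, which encodes an ATG8-family autophagy protein, and MAFG, a small MAF transcription factor gene, were 10.1-fold, 9.65-fold, 9.58-fold, 9.11-fold and 8.43-fold higher.

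Among the genes with the lowest ratios, CLDN2, which encodes the tight-junction protein claudin-2 (chromosome X, 106900164 to 106930861), went from 866 counts to 1, a ratio of 913 with an interval of 163 to 36113. The neuronal gene CEND1 (chromosome 11, 787104 to 790123) went from 160 counts to 3, a ratio of 56.2 with an interval of 18.9 to 276. LBH was 10.5-fold lower (7.58 to 14.8), ZBTB38, a zinc-finger protein gene, 8.59-fold (7.29 to 10.2), APC, the Wnt pathway tumour suppressor gene, 8.0-fold (5.76 to 11.4) and ZNF672 7.31-fold (5.70 to 9.49). ITGB6, the integrin beta-6 gene, was 6.75-fold lower, TGOLN2, a trans-Golgi protein gene, 6.54-fold and ID2, an inhibitor of basic helix-loop-helix factors, 5.88-fold. RP11-864I4.1 was 9.24-fold lower, EIF2S3L 8.85-fold and TOMM6 6.33-fold. CLDN2 overlaps MORC4, RP11-864I4.1 overlaps EEF1G and TOMM6 overlaps PRICKLE4, and EIF2S3L has a close relative in EIF2S3, so counting could split reads between the genes of each pair and the ratios of these 4 are uncertain. All 4 partner genes were named after their values were seen.

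**Figure D1:**
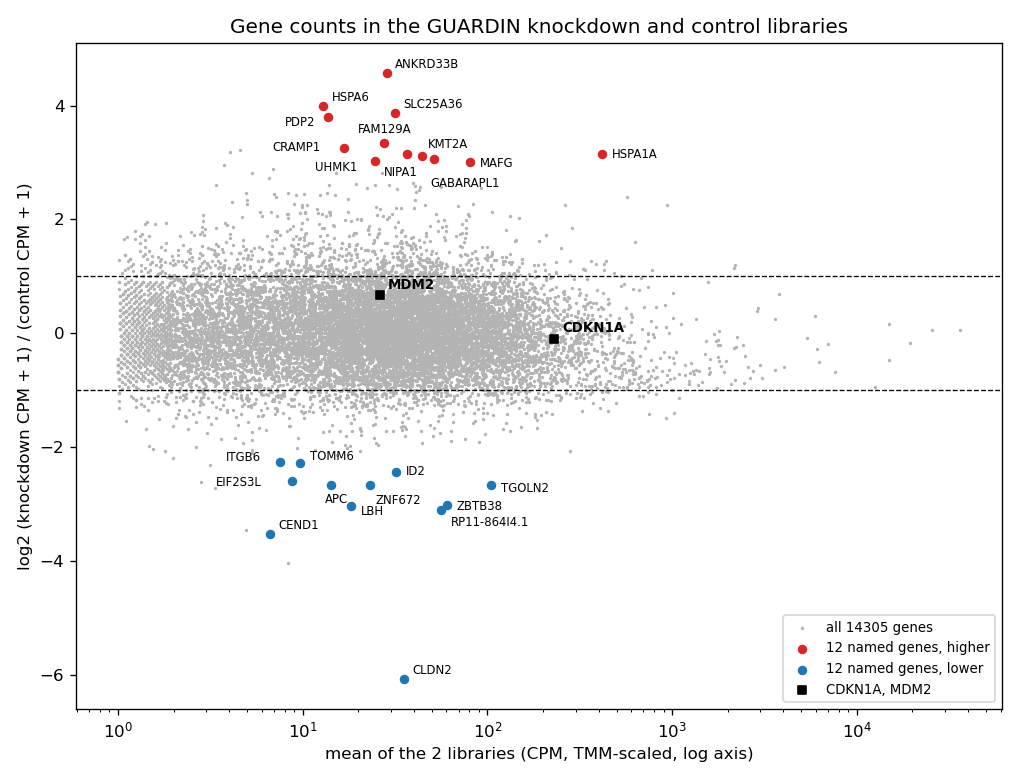
Each grey point is 1 of 14305 genes, with the mean of the 2 libraries in CPM on a log axis and the log2 ratio of knockdown over control on the vertical axis. Red and blue points are the 12 named genes with the highest and the 12 with the lowest ratios, dashed lines mark 2-fold, and CDKN1A (log2 ratio -0.10) and MDM2 (0.67) lie between them.

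Transcripts of ribosomal proteins and of the nuclear-encoded respiratory chain were lower in the knockdown library. All 43 large-subunit ribosomal protein genes were lower, with a median log2 ratio of -0.82, and so were 31 of 32 small-subunit genes, with a median of -0.83. RPS3A (2.78-fold lower, 2.60 to 2.97), RPS15A (2.57-fold), RPL30 (2.49-fold) and RPL31 (2.26-fold) had the lowest ratios, followed by RPS27A (2.24-fold), RPL34 (2.16-fold), RPL6 (2.15-fold) and RPS12 (2.12-fold). Of 40 nuclear genes for respiratory chain subunits 37 were lower, with a median of -0.64. UQCRC1 of complex III was 2.31-fold lower (2.16 to 2.47), NDUFA2 of complex I 2.27-fold, COX4I1 of complex IV 2.26-fold and ATP5G1 of the ATP synthase 2.06-fold. The medians of these 3 lists lay below those of all 10000 random lists of matched expression. Pooled over 115 genes their median was -0.76, against random medians of -0.24 to 0.02 with matching on expression alone and -0.58 to -0.39 with matching on mature transcript length as well. The 13 protein genes of the mitochondrial genome did not share the direction: 7 were higher and 6 lower, with a median of 0.06 that fell within the random range, and MT-ND4L and MT-ND6 were 2.21-fold and 1.70-fold higher. MT-ND4L overlaps MT-ND4, which had 171879 and 203203 counts, so counting could split reads between them and the ratio of MT-ND4L is uncertain. The list of mitochondrial genome genes stood apart as higher with the deposited FPKM (median 0.16, percentile 99.97), without the length trend (0.42, 99.99) and with mature length matched (99.98). Of 31 proteasome genes 29 were lower (median -0.46, percentile 1.12), among them PSMA4 and PSMA3 (each 1.91-fold), PSMB4 (1.84-fold) and PSMA7 (1.77-fold). None of the proteasome genes reached 2-fold, and the list lay within the random range with the deposited FPKM (percentile 8.66) and with random lists matched on mature transcript length as well (27.4).

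Genes of DNA replication, chromatin packaging and mitosis were lower. Of 34 replication genes 30 were lower, with a median of -0.43 at percentile 0.05. GINS2, a subunit of the replicative helicase complex, was 2.95-fold lower (2.61 to 3.35), the maintenance methylation factor gene UHRF1 2.71-fold and GINS4 2.47-fold. Of 33 core and linker histone genes in the list only 10 passed the filter, and all 10 were lower (median -0.73, percentile 0.02). HIST1H2BK was lower by 4.39-fold, HIST1H1C by 3.19-fold and HIST1H2AC by 2.24-fold. HIST1H2BJ had 32 and 13 counts. The size of the histone median depended on low counts and length: it was -0.32 with a pseudocount of 5, -0.34 without the low-value filter and -0.44 without the length trend, and stood apart in each. Of 30 G2/M genes 25 were lower (median -0.39, percentile 0.70). CDC20, an activator of the anaphase-promoting complex, was 2.40-fold lower, KIF20A 1.90-fold, and the mitotic kinase genes PLK1 and CDK1 were each 1.82-fold lower. LMNB1, which encodes lamin B1 of the nuclear envelope, was 1.79-fold lower (1.63 to 1.97). The G2/M list lay at the 5.07th percentile with the deposited FPKM and at the 6.76th after removal of the length trend, within the random range in both. The mesenchymal list had a median of -0.40 (percentile 1.02), with 17 of 27 genes lower. It was -0.25 without the low-value filter. Its members diverged: TPM1 was 2.32-fold lower, while FN1, which encodes fibronectin, was 5.27-fold higher (5.03 to 5.51) and CALD1 2.04-fold higher. It lay within the random range with the FPKM (percentile 9.13) and without the length trend (3.97).

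Genes of lipid synthesis and the heat-shock response were higher. Of 17 fatty acid synthesis genes 15 were higher (median 0.46, percentile 99.7), among them LPIN1 (3.60-fold, 3.16 to 4.12), the desaturase gene SCD (2.31-fold), ACSL3 (1.74-fold) and FASN (1.69-fold). Of 24 genes of cholesterol synthesis and uptake 16 were higher (median 0.32, percentile 98.3). INSIG1 was 2.91-fold higher (2.62 to 3.24) and HMGCS1 2.60-fold, while PMVK was 2.22-fold lower. The cholesterol list stood apart under every alternative, with a median of 0.50 with the deposited FPKM. The fatty acid median was 0.21 without the length trend, and with mature length matched this list lay within the random range (percentile 95.1). Of 19 heat-shock genes 15 were higher (median 0.16, percentile 98.0). HSPA1B was 3.63-fold higher and is nearly identical to HSPA1A, the co-chaperone gene BAG3 was 2.16-fold higher and HSPH1 1.94-fold. The heat-shock median was 0.27 with the FPKM, in which ratios lack the TMM shift of 0.11. The list lay at the 96.85th percentile with no filter on low values and at the 80.55th when random lists were not matched on expression.

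Of 13 genes of the RNA interference machinery 9 were higher (median 0.74, percentile 99.95), with TNRC6A, AGO4, TNRC6B and AGO3 at 3.11-fold, 2.84-fold, 2.36-fold and 2.30-fold. Its median was 0.41 with a pseudocount of 5. The list lay at the 96.9th percentile after removal of the length trend and at the 95.6th with the FPKM. Of 21 NF-kB targets 11 were higher and 10 lower (median 0.42, percentile 99.3). That median is the smallest ratio among the higher genes, so the placement rests on a near-even split and does not show a rise of the list as a whole. The adhesion molecule gene ICAM1 was 3.29-fold higher, NFKB2 and BIRC3 were each 1.90-fold higher and TNFAIP2 was 1.98-fold lower. Of 21 FOXO targets 13 were higher (median 0.36, percentile 97.6), among them BCL6 (3.67-fold), PDK4 (2.46-fold), CCNG2 (2.28-fold) and IRS2 (2.13-fold). After removal of the length trend these lists lay at the 95.8th and 82.3rd percentiles. Without the low-value filter they lay at the 96.5th and 97.4th, within the random range.

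**Figure D2:**
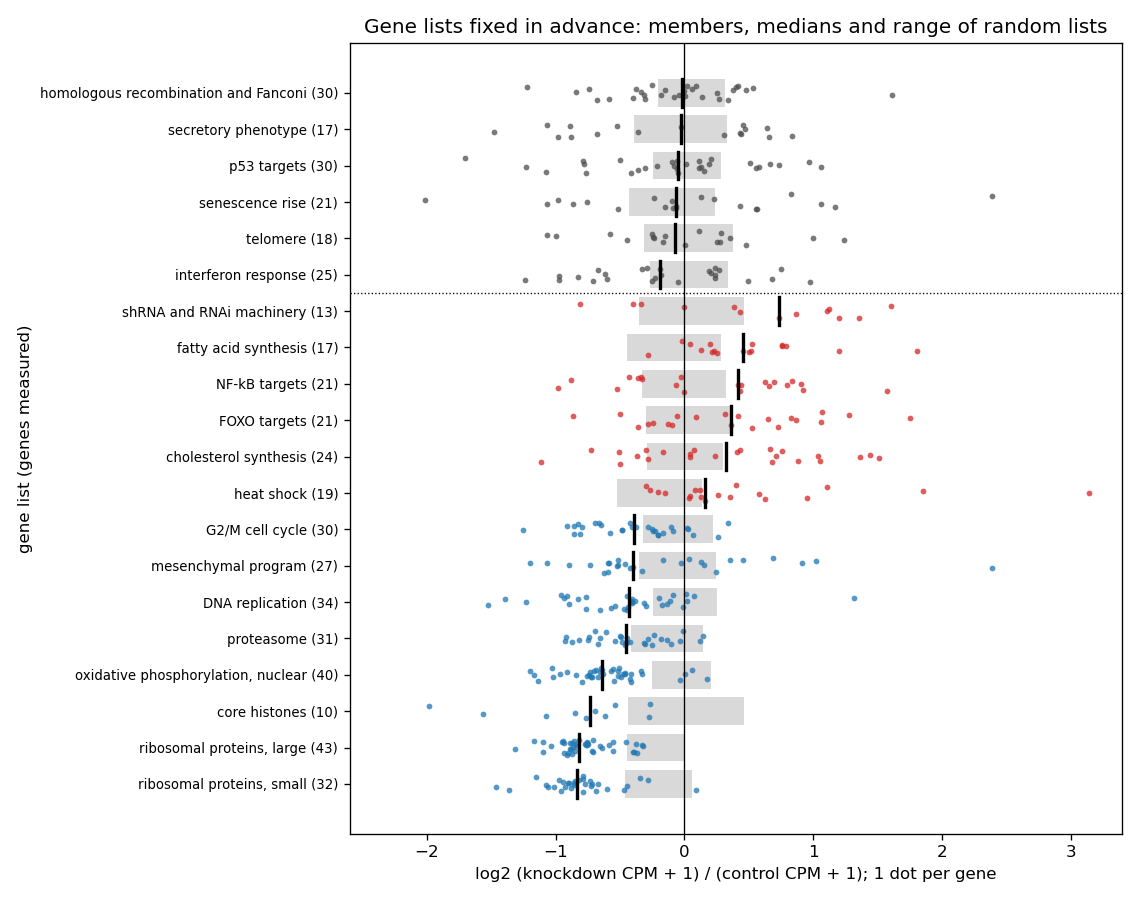
Each dot is the log2 ratio of 1 gene, by list, with the number of measured genes in parentheses; black bars are list medians and grey boxes span the central 95% of the medians of matched random lists. Below the dotted line are the 14 lists that stood apart, from the small ribosomal subunit at -0.83 to the RNA interference machinery at 0.74, and above it 6 lists within the random range.

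The genes linked to GUARDIN and p53 in published work did not stand apart as lists in the comparison as planned. CDKN1A, which encodes the p53-induced cell cycle inhibitor p21, had 2891 counts in the control and 2849 in the knockdown, 1.07-fold lower (1.02 to 1.13), a difference no larger than the 0.11 on the log2 scale by which scaling moved all genes. MDM2, a p53 target, was 1.62-fold higher (1.38 to 1.90). The 30 p53 targets had a median of -0.05, with 14 higher and 16 lower. FDXR was 3.34-fold lower (2.97 to 3.76) and TP53I3 2.38-fold lower (2.13 to 2.66). FOXO4 was 3.23-fold higher (1.99 to 5.46) at 22 and 75 counts, and the coactivator gene PPARGC1A 3.15-fold higher (2.05 to 4.99) at 28 and 93. Its partner gene LRPPRC was 1.12-fold higher (1.08 to 1.17). TERF2, which encodes a telomere-binding protein, was 1.41-fold higher (1.21 to 1.65). BRCA1 was 1.10-fold higher (0.969 to 1.25) and BARD1 1.21-fold lower (0.975 to 1.49), with intervals that include no difference. The DNA damage kinase gene ATM was 4.95-fold higher (4.1 to 6.02). The 16 genes of this published axis had a median of 0.32 at percentile 95.9. It was 0.15 (percentile 74.6, 14 genes) at a mean of at least 5 CPM, 0.15 (68.2, 13 genes) with the FPKM and 0.06 (70.7) without the length trend, while with mature length matched the list stood apart as higher (98.8).

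Lists for senescence, DNA repair and telomeres lay within the random range. The median was -0.07 for 21 genes often higher in senescent cells, in which FN1 was higher and IGFBP7 4.53-fold lower, and -0.02 for 17 secretory phenotype genes, in which IL11 was 4.16-fold lower. With the FPKM the secretory median was 0.21 (percentile 97.42, 14 genes), at the edge of the random range. Homologous recombination and Fanconi genes had a median of -0.02, with BRCA2 3.41-fold higher and FANCL 2.44-fold lower. End-joining genes had a median of 0.03, with TP53BP1 1.65-fold higher and C9orf142 1.88-fold lower. Telomere genes had a median of -0.07, with TNKS 2.40-fold higher and NHP2 2.11-fold lower. Apoptosis genes had a median of -0.02, with XIAP 3.13-fold and the death receptor gene TNFRSF10B 1.96-fold higher. The list for mitochondrial biogenesis had a median of -0.07, and the mitochondrial transcription factor gene TFAM was 1.92-fold lower.

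Other lists within the random range held single genes with large ratios. TXNRD1, a thioredoxin reductase gene, was 4.77-fold higher (4.61 to 4.93) and HMOX1 2.34-fold higher among NRF2 targets, whose median was -0.26 (percentile 36.3). The NRF2 median was -0.16 (95.6) with the FPKM and -0.15 (76.6) without the length trend. BNIP3L was 4.36-fold higher and ALDOC 3.27-fold lower among hypoxia and glycolysis genes, with a median of -0.01. In the list for unfolded protein and amino acid stress 21 of 30 genes were higher (median 0.12, percentile 89.5), with HERPUD1 at 3.24-fold and DNAJB9 at 3.15-fold. That list stood apart as higher with the FPKM (percentile 99.4), without the length trend (99.3) and with mature length matched (98.9). Immediate early genes had a median of 0.17, with EGR1 4.1-fold and SPRY4 3.39-fold higher. WIPI1 was 2.24-fold higher among lysosome and autophagy genes (median -0.14), and BOP1 and NIP7 were 2.87-fold and 2.02-fold lower among ribosome biogenesis genes (-0.22, lower than the random range with mature length matched, percentile 2.29). IFI6 and IFI35 were 2.62-fold and 2.06-fold lower among interferon response genes (-0.19), and PSMB10 and HLA-F 2.35-fold and 1.83-fold lower in antigen presentation (0.09). The interferon median was -0.06 with the FPKM and 0.01 without the length trend, and that of antigen presentation was -0.07 without the length trend. OCLN, a tight-junction gene, was 4.13-fold higher in the epithelial list (-0.03), and PMEPA1 was 3.14-fold lower among TGF-beta and YAP targets (0.01). The mucin genes MUC5B and MUC5AC were 3.21-fold and 2.19-fold higher in the lung lineage list (0.37), and APOE and FGA 2.27-fold and 1.60-fold higher among liver-type secreted proteins (0.23). The lung list depended on the choices made: its median was 0.04 (percentile 66.7, 18 genes) without the low-value filter and 0.21 (92.2) with a pseudocount of 5. It stood apart as higher with the FPKM (0.49, percentile 97.6, 7 genes) and without the length trend (0.43, 98.2), but lay at the 82.8th percentile with mature length matched. The liver-type median was 0.00 without the filter.

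The log2 ratio increased with gene-model length, the length implied by the deposited FPKM, which exceeds the locus of some genes. The median was -0.40 in the decile of shortest gene models and 0.39 in the decile of longest. Spearman's rho across the 14305 genes, which are not independent replicates, was 0.35. With mature transcript length, over 12333 genes, it was higher, at 0.489. The trend removed in this report is the one with gene-model length, so removal leaves part of the length dependence in place. After its removal 759 genes were at least 2-fold higher and 493 at least 2-fold lower. Among abundant nuclear RNAs, MALAT1 was 2.11-fold higher (2.0 to 2.23) and MEG3 2.02-fold, but their list had a median of 0.22 within the random range, which turned to -0.15 (13 genes) without the low-value filter, -0.23 (9 genes) with the FPKM and -0.04 without the length trend. The 20 housekeeping genes had a median of -0.36 (percentile 12.6), with TUBB 1.85-fold and YWHAZ 1.82-fold lower. They stood apart as lower against unmatched random lists (percentile 1.03) and without the length trend (-0.52, percentile 1.08).

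**Figure D3:**
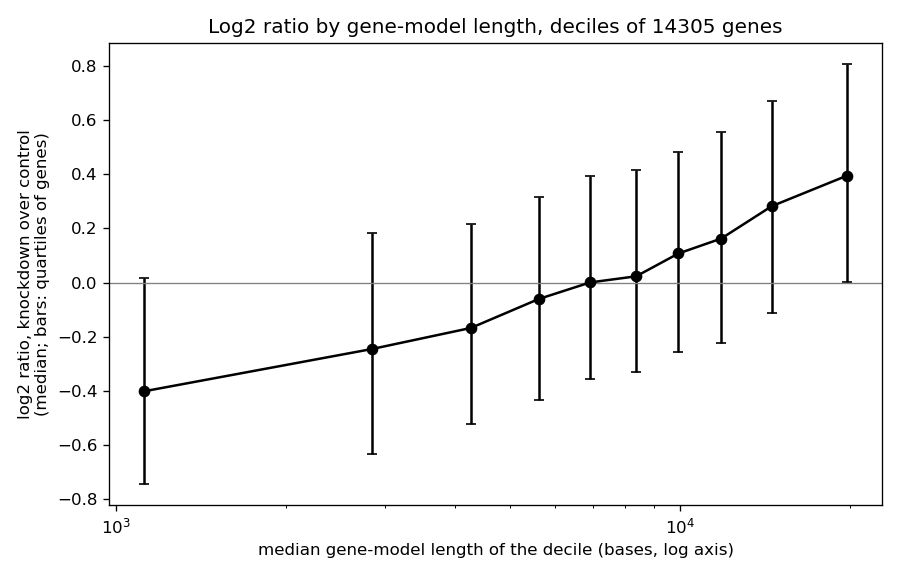
Points are median log2 ratios of knockdown over control in 10 groups of genes, and bars span the quartiles of genes. Groups are ordered by gene-model length, the length in bases implied by the deposited FPKM, on a log axis. The median goes from -0.40 in the shortest to 0.39 in the longest group.

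Of 20 leukocyte markers 6 reached 1 CPM in either library, up to 17.9 CPM in the control and 11.5 in the knockdown, and CD14 and ITGAM had 121 and 35 counts in the control against 49 and 87. Of 18 stromal and endothelial markers 4 reached 1 CPM, with ACTA2 at 31.6 and 16.5 CPM and COL1A1 at 199 and 143 counts. Of 21 markers of other cell lines 5 reached it. Of these, NEFL had 32 and 18 counts. Medians of the 4, 3 and 5 markers past the filter were -0.46, -0.51 and -0.12.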

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

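Each group had 1 library, so depth and the lack of replicates limit every value, and no library could be left out. No paired analysis was possible because each group has a single library with no shared replicate number in the labels. Directions of all named genes at 2-fold or more held under every alternative in which they were computed, which says little. Pseudocounts and filters cannot turn a ratio, and scaling moved ratios by at most 0.11 on the log2 scale. Ratios of named genes were not computed without the length trend. Of 1054 values of named genes under the alternatives, 165 moved beyond their counting interval, 109 with the deposited FPKM, 52 with a pseudocount of 5 and 4 with median-of-ratios scaling. The targeted transcript had a log2 ratio of -1.23 with a pseudocount of 0.1 and -0.61 with median-of-ratios scaling, against -0.60. Neither change could turn its direction. The count of genes at least 2-fold higher was 479 with a pseudocount of 5 and 387 with the FPKM, against 932. The count at least 2-fold lower was 905 with a pseudocount of 0.1, 277 with 5 and 250 with the FPKM, against 591. A pseudocount of 1 FPKM weighs more for long genes and fewer genes (11362) passed that filter. The FPKM also lacks the TMM scaling, which raises its log2 ratios by up to 0.11. Of 397 list placements, 368 stayed on their side of the percentile limits. The ribosomal, nuclear respiratory chain, histone, replication and cholesterol lists stood apart under all alternatives run. With a pseudocount of 5, FOXO targets were within range (median 0.23). Without a filter, NF-kB targets (0.24), heat shock (0.15) and FOXO targets (0.36) were within range, as were FOXO targets with rows of 1 symbol summed (0.36). With the FPKM, the G2/M (-0.28), proteasome (-0.34), mesenchymal (-0.23) and RNA interference (0.46) lists were within range, while unfolded protein stress (0.20), mitochondrially encoded respiratory chain (0.16) and lung lineage (0.49) stood apart as higher. With unmatched random lists, heat shock (0.16) was within range and housekeeping (-0.36) stood apart as lower. With the length trend removed, a choice made after seeing the data, the G2/M (-0.29), NF-kB (0.22), FOXO (0.15), mesenchymal (-0.31) and RNA interference (0.35) lists were within range, and unfolded protein stress (0.21), mitochondrially encoded respiratory chain (0.42) and lung lineage (0.43) stood apart as higher and housekeeping (-0.52) as lower. With random lists matched on mature transcript length as well, also chosen late, fatty acid synthesis (0.46) and proteasome (-0.46) were within range, while the study axis (0.32), unfolded protein stress (0.12) and mitochondrially encoded respiratory chain (0.0578) stood apart as higher and ribosome biogenesis (-0.22) as lower. Over all alternatives 44 list medians moved by more than 0.1 and changed sign or size by more than 1.5 times, of which 13 changed sign, none in a list that then stood apart. With the FPKM, the missing TMM scaling accounts for up to 0.11 of such a move. Other causes were not tested. The leukocyte and stromal lists had too few genes to rank, and the list of other cell lines had too few with the FPKM or a mean of at least 5.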

Other observations

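The family medians, the tests on 3′ UTR length and GC content, on motif copies, on overlapping genes and on the hairpin, and the bootstrap criterion for mature transcript length were chosen after the results were seen. Matching of families on mature length was added last. Families of at least 15 genes with a shared symbol stem, outside the fixed lists, also parted in direction. Of 67 such families 16 stood apart from random lists matched on expression, where 3.35 would by chance if genes varied independently. Genes of a family may vary together, so an excess over chance cannot be read from this. Of the 16, 11 did so with matching on gene-model length as well and 7 with matching on mature transcript length instead. Mitochondrial ribosomal protein genes were lower, with a median log2 ratio of -0.63 over 48 MRPL genes (percentile 0.15 with mature length matched) and -0.57 over 29 MRPS genes (0.985), as were 24 METTL genes (-0.41, 0.11). Histone demethylase genes of the KDM family were higher, with a median of 0.82 over 17 genes (percentile 99.8), against random medians of 0.03 to 0.64 with mature length matched. KLHL genes (0.52 over 24) and ZNF genes (0.25 over 373) were also higher and stood apart with each length matched. NUDT (-0.39), COL (0.56), ZBTB (0.45), USP (0.44) and KIF (0.40) did so with gene-model length only and SEC (0.31) with mature length only, so length may account for them. POLR (-0.33), ANKRD (0.30), MAP (0.33) and ARHGAP (0.48) stood apart only with matching on expression. REL, an NF-kB subunit gene named after its values were seen, had 0 counts in the control and 105 in the knockdown, with a lower bound of 26.5-fold from the exact interval. It overlaps RP11-373L24.1, which had 121 and 101 counts.

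The ribosomal protein and nuclear respiratory chain genes, pooled over 115 genes, had a median log2 ratio of -0.76. Against lists matched on mean CPM and gene-model length the pooled median lay at percentile 0 (random range -0.33 to -0.08). Genes matched on mature transcript length were themselves lower, with random medians of -0.58 to -0.39, so a trend with transcript length may carry a large part of the pattern. The criterion set beforehand against it as the whole cause was not met, because the members' upper quartile of -0.55 lay inside that range; only by the later criterion, a bootstrap interval of the pooled median (-0.82 to -0.71, percentile 0), does the pattern exceed it. Adding the counts of 401 pseudogenes named after these genes left the pooled median at -0.77, which argues against reads lost to pseudogenes, while a difference in library preparation and an effect of the knockdown both stay open with 1 library of each.

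Messenger RNAs with the AU-rich motif TATTTAT in the 3′ UTR were higher, and the motif ranked first for higher ratios among 14326 7-mers scanned in 12196 3′ UTRs. Carriers had a median log2 ratio of 0.26 and non-carriers of -0.08, and matching on 3′ UTR length and GC content reduced this gap of 0.34 to 0.13 (quartiles of genes -0.25 to 0.51), so these properties may carry most of it. The motif's score of 9.27 lay above 4.88, the highest score of any 7-mer in 50 shuffles within bins of both properties. The rest of the gap therefore exceeded these properties, and the shuffles allow for the motif's choice among all 7-mers. Mature transcript length, with which the log2 ratio also rose, was neither matched nor held in the shuffles. Whether it accounts for the rest was not tested. A class effect of AU-rich element mRNAs that grows with motif copies cannot be told apart from a flat one, since 3 or more copies exceeded 1 copy by 0.0438 with a bootstrap interval of -0.01 to 0.09, a test that replaced one without an interval. Carriers of Alu repeat words were higher before matching (median 0.15) and lower than matched 3′ UTRs by 0.17 (quartiles -0.55 to 0.19).

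The most extreme ratios might come from reads moved between overlapping genes or from an off-target effect of the hairpin. Of the 24 named genes 17 had no counted overlapping gene. The test did not cover similar genes elsewhere, such as EIF2S3 for EIF2S3L or HSPA1B for HSPA1A. For 3 genes (CLDN2, RP11-864I4.1 and TOMM6) the overlapping genes held counts enough for 0.5 of the change, which argues against reads moved to an overlapping gene for the other 21. For these 3, moved reads cannot be told apart from other causes: the overlapping genes were lower too (the highest opposite share was -0.23; MORC4 went from 1455 to 1324, EEF1G from 9486 to 9130 and PRICKLE4 from 964 to 529), but a change of their own could hide a gain. For an off-target seed, the 7-mer with the most negative mean effect in 3′ UTRs without Alu words was AAGACGA, at -0.20 over 212 genes against a lowest value of -0.18 in 50 shuffles, a limit that replaced an earlier one after its result was seen. It occurred in 1 of the 11 searched 3′ UTRs of the 12 named lower genes, ZNF672, and a seed effect cannot be told apart from other causes without the hairpin sequence, which is not given in the sources used here.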
